A study of Homo sapiens with 55 samples.

How the data were processed

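The series holds 55 Illumina HumanHT-12 v3 arrays in 14 groups, with 4 arrays in each group except the SCL60 1 h controls, which have 3. Values were taken from the table of non-normalized signals that the authors deposited, in which each array has an intensity on a linear scale and, per the file headers, a detection p-value for each of 48803 probes. The intensity had not been background subtracted; at least 99.996 percent of values were whole numbers on each of the 33 arrays of hybridisation batch 1, and nearly all were decimals on the 22 arrays of batch 2. A second deposited table, of values quantile normalized by the authors, kept the order of the probes on every array (Spearman correlation 1) and was used as an alternative source. Array medians ran from 44 to 75, and between 11766 and 14763 probes per array were detected at a p-value under 0.01 (median 13375). Correlations between replicate arrays ran from 0.953 to 0.993, and no 2 arrays held identical signals.

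Signals were corrected for background by the normexp method of limma (3.58.1, in R 4.3.3), with the negative controls inferred from the detection p-values and an offset of 16, then quantile normalized and put on a log2 scale. Probes detected on at least 3 arrays were kept (16016). Probes were given the gene symbol of the annotation table, and the probe with the highest mean signal, chosen without regard to group, stood for each gene, which left 10467 named genes and 2326 probes without a symbol, 12793 in total. Fold changes are differences of group means on this scale; where the lower group was undetected on any array, the fold is given as at least that left when values under the lowest detected value of an array are raised to it. Log2 differences are as fitted. The folds for groups undetected on some arrays alone were added after the results had been seen. Rat receptor transcript from the transgene is not measured by these probes.

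A linear model with 1 mean per group was fitted to all 55 arrays, and contrasts were tested with limma's moderated t test with an intensity trend and the Benjamini-Hochberg adjustment, at an adjusted p of 0.05. Triptorelin at 0.5, 1 and 2 h in SCL60 was compared with the 1 h controls, so these 3 comparisons share their control arrays. No overlap between them was tested. The series has no 0.5 h or 2 h controls, so at those times the comparisons do not separate time or handling from triptorelin. The comparisons at 8 h and 24 h used controls of the same time, as did those in HEK293 at 1 h and 24 h. Differences of effects, between the lines and between times, were tested as contrasts of their own. They are signed, so a lower or smaller effect can be a deeper fall, and a higher or larger one a lessened fall. Named genes were the 10 largest rises and 10 largest falls in SCL60 at 1, 8 and 24 h and the 5 largest elsewhere, among genes that passed, were detected on every array of a compared group and had every array of the first group on the same side of the second group's mean; the last condition was not used for differences of effects. From each list up to 4 passing members with the largest change were named, or up to 2 as values, and GNRHR, FSHB, LHB and CGA wherever measured. The differences of the 1 h and 0 h controls were looked at, and their genes named, after the values had been seen.

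Gene lists were tested with camera, with a preset correlation of 0.01 and again with an estimated correlation, and adjusted over the lists of a comparison. Camera p-values are those with the preset correlation unless stated. An estimated correlation could raise them by many orders of magnitude, so their size does not measure the strength of a change. For immediate early genes in SCL60 controls at 1 h against 0 h, the camera adjusted p was 3.34e-26 with the preset and 5.56e-05 with the estimate. The 24 lists, written from general knowledge of gene function, were immediate early genes, MAPK feedback regulators, calcium and cAMP response genes, NF-kappaB pathway and targets, growth arrest genes, G1/S and DNA replication, G2/M and mitosis, pro-apoptotic genes, anti-apoptotic genes, p53 targets, ER stress and amino acid response, cholesterol synthesis, SRF and YAP/TEAD targets, secreted growth factors, matrix and protease genes, ribosome biogenesis, oxidative phosphorylation, hypoxia and glycolysis, heat shock and oxidative stress, interferon response, neuronal and neuroendocrine genes, epithelial markers, fibroblast markers and blood cell markers. They held 582 members, of which 429 were tested; the fibroblast and blood cell lists had fewer than 5 tested members and were given as values alone. Groups, comparisons, lists, thresholds, the rule for naming genes and the alternatives were fixed before the data were examined.

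Alternatives were no background correction, the authors' normalized values, cyclic loess, no filter and a stricter filter on dim probes, all probes, the replicate number, chip or labelling batch as a block, only the groups compared, other control groups, and leaving out each array in turn. Arrays of a comparison were also divided into groups in all other ways, or in 100 random ways for differences of effects, and tested alike. Effects were recomputed within each hybridisation and labelling batch; these are subsets of the arrays on which the genes were chosen, so agreement of sign there was largely fixed beforehand and is no test of a batch effect. The fit was tested on simulated data with 200 of 12793 genes changed: at 1 h it recovered 13.6, 79.1 and 100.0 percent of changes of 0.5, 1 and 2 on the log2 scale with 3.73 percent false calls, at 8 h 12.1, 82.1 and 100.0 percent with 4.41 percent false, at 24 h 22.7, 76.1 and 100.0 percent with 5 percent false, at 0 h 18.2, 79.1 and 100.0 percent with 5.04 percent false, and for the difference of the lines at 24 h 10.6, 46.3 and 95.5 percent with 7.27 percent false. A list shifted by 0.5 was called in each of these 5 simulations and no other list was. Genes were drawn independently and without replicate or batch effects, so these runs could not show false calls from such structure. Nothing in the sample records says that replicates were separate cultures, so p-values measure only the spread between these samples. Protein, phosphorylation and cell growth were not analysed here.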

Results

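The series compared SCL60 cells, a HEK293 derivative that carries a stably transfected rat gonadotropin-releasing hormone (GnRH) receptor, with parental HEK293 cells, before and after the GnRH agonist triptorelin (100 nM) or its vehicle. The comparisons address which transcripts change when the receptor is activated, when they change, and whether cells without the transgene change as well. The largest counts of genes changed by triptorelin were in SCL60 cells at 8 h (3159 genes) and 24 h (1337 genes), while no gene passed the test in HEK293 cells at 1 h or 24 h. Probes for human GNRHR, FSHB and LHB were detected on none of the 55 arrays; the GNRHR probe was designed for the human transcript, so it says nothing about the rat transgene.

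**Figure D1:**
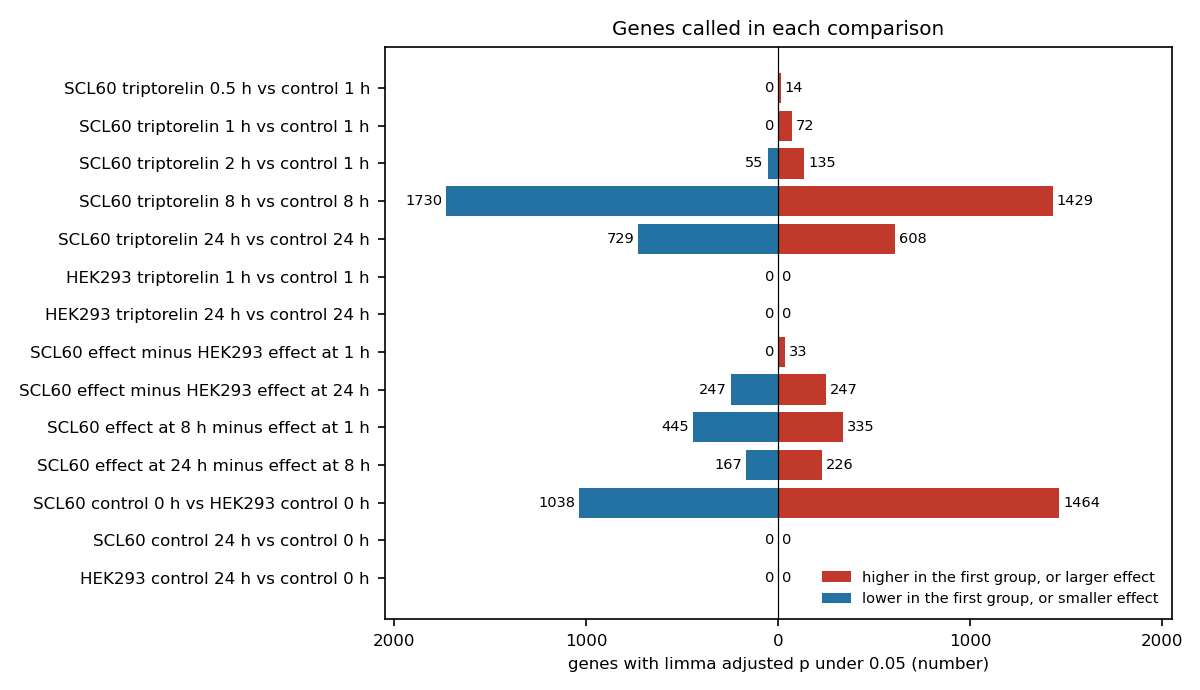
Number of genes with a limma adjusted p under 0.05 in each of the 14 comparisons (horizontal axis). Genes higher in the first group, or with a positive difference of effects (larger effect in the key), lie to the right. Genes lower, or with a negative difference of effects (smaller effect in the key), lie to the left. Comparisons of triptorelin with control called between 14 and 3159 genes in SCL60 cells and 0 in HEK293 cells. Those at 0.5 h and 2 h used the 1 h controls, so time and triptorelin are not separated in them.

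After 1 h of triptorelin, SCL60 cells (n = 4) held more transcript of immediate early transcription factors than SCL60 cells given vehicle (n = 3). FOSB, a subunit of the AP-1 transcription factor, rose 74.7-fold (log2 difference 6.22, SE 0.34, limma adjusted p 7.3e-20), and its relatives FOS and JUNB rose at least 22.3-fold and at least 7.22-fold. The control arrays of FOS and FOSB lay far apart: without control 1 h replicate 3 the rise of FOSB was 129.1-fold, and without replicate 2 that of FOS was 13.7-fold. The orphan nuclear receptor genes NR4A2 and NR4A1 rose at least 20.5-fold and at least 5.50-fold. EGR3, another transcription factor gene, rose by 3.96 on the log2 scale on the probe tested, while its other probe gave 0.39 and did not pass. PTGS2, the inducible cyclooxygenase, rose at least 13.2-fold, and DUSP1, a phosphatase that inactivates MAP kinases, rose 7.07-fold. CGA, which encodes the alpha subunit shared by the pituitary and placental glycoprotein hormones, was undetected in control cells and rose at least 3.64-fold. Probes without a gene symbol were also among the largest rises, ILMN_1743199 (at least 12.8-fold) and ILMN_2410145 (at least 4.54-fold).

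Of the 28 tested immediate early genes, 17 rose at 1 h and 11 did not pass (25 rose when adjusted over the list alone, camera adjusted p 3.59e-186). The MAPK feedback regulators rose in 5 of 13 (7 adjusted over the list alone), among them DUSP5 (log2 difference 2.44), IER3 (1.13) and SPRY2 (1.12), with a camera adjusted p of 1.02e-28. Among calcium and cAMP response genes 4 of 15 rose (6 adjusted over the list alone, camera adjusted p 1.22e-24). RGS2, a brake on G protein signalling, rose by 1.59, SIK1 by 1.58 and GEM by 1.32 on the probe tested (0.19 and 1.10 on its others). In the NF-kappaB list 5 of 20 rose (5 adjusted over the list alone, camera adjusted p 3.1e-07), including the chemokines CCL2 (1.69) and CXCL8 (1.64), NFKBIZ (1.34) and GADD45B (1.24). Growth arrest genes rose in 4 of 26 (8 adjusted over the list alone, camera adjusted p 9.75e-16), with the antiproliferative BTG1 at 1.21, GAS1 at 1.07 and MXD1 at 0.62. MCL1, an anti-apoptotic BCL2 relative, was the 1 member of its list of 14 to rise (log2 difference 1.82, adjusted p 3.93e-09; camera adjusted p for the list 0.16, and 1 adjusted over the list alone). No pro-apoptotic gene passed the test over all genes (PMAIP1 1.02, adjusted p 0.126; 1 rose adjusted over the list alone), and the list's camera adjusted p of 0.0496 became an adjusted p of 0.113 with an estimated correlation.

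ER stress and amino acid response genes rose in 2 of 24 at 1 h (2 adjusted over the list alone), DNAJB9 (1.56) and PPP1R15A (1.37). Their camera adjusted p was 0.0158, with an adjusted p of 0.508 with an estimated correlation. Their median was 0.07 within hybridisation batch 1 and -0.24 within batch 2. In the SRF and YAP/TEAD list, CCN1 alone rose (log2 difference 2.40; 1 of 17, and 1 adjusted over the list alone). The list's mean was 0.23 and its median -0.02, and its camera adjusted p of 0.0198 became an adjusted p of 0.203 with an estimated correlation. The secreted factors, of which 0 passed over all genes and 3 rose adjusted over the list alone (HBEGF 0.65, BMP2 0.65), had a camera adjusted p of 0.000742. The hypoxia and glycolysis list, with 0 and 1 in the same counts (ANKRD37 0.66, ADM 0.50), had 0.00173. Cholesterol synthesis genes (0 of 16 over all genes, 2 rising adjusted over the list alone, camera adjusted p 0.0322) had an adjusted p of 0.113 with an estimated correlation. G1/S genes (0 of 29, 1 rising adjusted over the list alone, camera adjusted p 0.0194) had one of 0.142.

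In all, limma called 72 of the 12793 genes and unnamed probes tested at 1 h, all of them rising, 43 at least 2-fold. All 72 had the same sign within hybridisation batch 1 and within batch 2 (median log2 rise 1.24 and 1.08, against 1.22 over all arrays), where batch 2 held 1 of the control arrays. The count was 46 without SCL60 control 1 h replicate 2 and 43 when only these groups were fitted.

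At 0.5 h, the earliest time, 14 genes rose, 8 of them members of the immediate early list. No 0.5 h controls exist, so time and handling are not separated from triptorelin here. FOS rose at least 34.0-fold (log2 difference 5.12, SE 0.39, limma adjusted p 7.96e-14) and FOSB 21.5-fold against the 1 h controls, followed by DUSP1 (5.75-fold), NR4A2 (at least 5.35-fold) and JUNB (at least 3.90-fold). Without control 1 h replicate 2 the rise of FOS was 20.9-fold, and without replicate 3 that of FOSB was 37.2-fold. The 1 h controls themselves lay above the 0 h controls for FOSB (log2 difference 1.73) and FOS (1.43, not called), so these folds depend on the control used. PTGS2 (log2 difference 1.45 on the probe tested and 0.58, not called, on its other probe) and ADM, a secreted vasodilator peptide (0.66), also rose. CGA was undetected and gave 0.14 (adjusted p 1). Of the 28 immediate early genes, 8 rose (16 adjusted over the list alone, camera adjusted p 1.05e-65). In the MAPK feedback list 1 of 13 rose (2 adjusted over the list alone, camera adjusted p 1.81e-08). In the growth arrest list 0 of 26 passed over all genes and 2 rose adjusted over the list alone (camera adjusted p 0.00125; BTG1 0.61, RHOB 0.56). Limma called no falling gene, and 12 of the 14 rose at least 2-fold. Against the 0 h controls the count was 26, against the mean of the 0 h and 1 h controls 28, and it was 5 when only these groups were fitted. Within hybridisation batches 1 and 2 all 14 kept their sign (median log2 rise 2.05 and 1.16, against 1.78 over all arrays).

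At 2 h, again against the 1 h controls, falling as well as rising genes were called. No 2 h controls exist, so neither can be assigned to triptorelin apart from time and handling. FOSB (27.5-fold, log2 difference 4.78, SE 0.34, limma adjusted p 3.67e-15), PTGS2 (at least 13.4-fold), NR4A2 (at least 12.9-fold), CXCL8 (11.4-fold) and CGA (at least 8.21-fold) rose most. FOSB rose 47.6-fold without control 1 h replicate 3, and was itself 1.73 higher on the log2 scale in the 1 h than in the 0 h controls. Among the largest falls, FOXD2 fell by 1.43 on the log2 scale (2.69-fold), DEPP1 by 1.41, the TGF-beta inhibitor SMAD7 by 1.22 (-0.30, not called, on its other probe), RUNX1T1 by 1.18 and FOXF2 by 1.07. Immediate early genes rose in 14 of 28 and fell in 1 (20 and 2 adjusted over the list alone, camera adjusted p 5.33e-37). MAPK feedback regulators rose in 7 of 13 (10 adjusted over the list alone; 2.45e-23), including IER3 (1.97), SPRED1 (1.20) and SPRY4 (1.13). Calcium and cAMP response genes rose in 7 of 15 (9 adjusted over the list alone; 7.67e-19), including HOMER1 (1.08).

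NF-kappaB targets rose in 6 of 20 at 2 h (9 rose and 1 fell adjusted over the list alone, camera adjusted p 5.36e-10), with CCL2 at 2.16 and GADD45B at 1.33. In the growth arrest list 5 of 26 rose and 1 fell (5 and 3 adjusted over the list alone, camera adjusted p 0.0835). GADD45A rose by 1.22 and the cell cycle inhibitor CDKN1B fell by 0.98 on the probe tested (-0.32, not called, on the other). PMAIP1, which encodes the BH3-only protein NOXA, rose by 1.53 as the 1 called member of the 21 pro-apoptotic genes (3 rose and 1 fell adjusted over the list alone, camera adjusted p 0.0283, and adjusted p 0.0874 with an estimated correlation). ER stress genes rose in 3 of 24 (7 adjusted over the list alone), DDIT3 (2.11), DNAJB9 (2.04) and PPP1R15A (1.13). The list had a camera adjusted p of 4.77e-08 and an adjusted p of 0.168 with an estimated correlation. Its median was 0.71 within hybridisation batch 1 and -0.04 within batch 2, which held 1 control array (0.32 over all arrays). SRF and YAP/TEAD targets rose in 2 of 17 (6 adjusted over the list alone, camera adjusted p 2.33e-06), THBS1 (at least 1.74-fold) and FHL2 (0.84). The G2/M list (0 of 32 called by either count) had a camera adjusted p of 0.00638, and an adjusted p of 0.194 with an estimated correlation. Its median was -0.34 within hybridisation batch 1 and 0.04 within batch 2. The ribosome biogenesis list (0 of 19 by either count) had a camera adjusted p of 0.0283, and 0.319 with an estimated correlation.

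Limma called 190 genes at 2 h, 135 rising and 55 falling, and 75 and 6 of them changed at least 2-fold. The falls were 32 without SCL60 control 1 h replicate 3, and those of at least 2-fold ran from 3 without that array to 14 without replicate 2. With the replicate number as a block, the numbers pairing these samples, the count was 422, all 190 among them. The count was 101 without SCL60 control 1 h replicate 4 (87 rising and 14 falling), 80 with only these groups fitted (71 and 9) and 447 against the mean of the 0 h and 1 h controls. All 190 kept their sign within hybridisation batches 1 and 2, with median log2 rises of 1.09 and 1.04 (1.07 over all arrays) and median falls of -0.86 and -0.70 (-0.80 over all arrays).

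**Figure D2:**
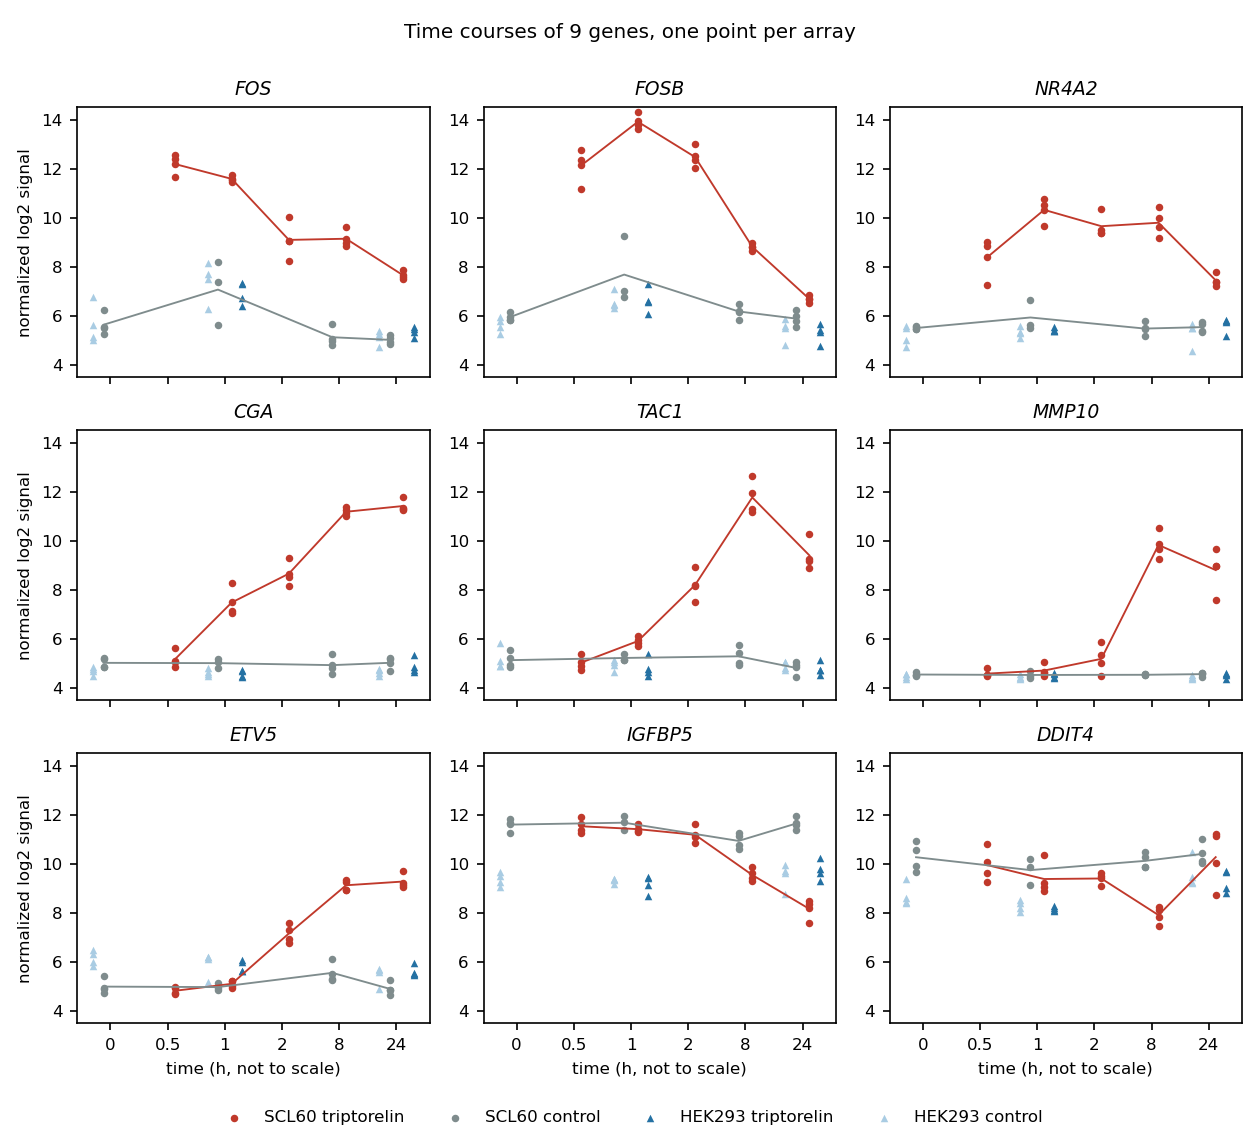
Normalized log2 signal (vertical axis) by time in h (horizontal axis, not to scale) for 9 genes; each point is 1 array, lines join the SCL60 group means, circles are SCL60 and triangles HEK293. In SCL60 given triptorelin, FOS was highest at 0.5 h and FOSB at 1 h, and CGA was detected from 1 h and reached a mean of 11.4 at 24 h. The 2 HEK293 groups given triptorelin stayed near their controls.

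After 8 h of triptorelin the response in SCL60 cells was broad (n = 4 and 4). TAC1, the precursor of the neuropeptide substance P, was detected on 1 of 4 control arrays and rose at least 67.3-fold (log2 difference 6.47, SE 0.27, limma adjusted p 3.32e-25), CGA at least 46.8-fold, C11orf96 at least 38.8-fold, the matrix metalloproteinase gene MMP10 at least 18.3-fold and the transcription cofactor gene LBH at least 31.0-fold. PTGS2 (at least 21.9-fold), NR4A2 (at least 17.1-fold), FOS (at least 11.2-fold, with 1 of 4 control arrays detecting it), ARC (at least 14.7-fold) and CXCL8 (at least 14.4-fold) completed the 10 largest log2 differences. The largest falls were LRRC20 (5.91-fold; log2 difference -2.56, SE 0.18, adjusted p 3.1e-16), DDIT4, an inhibitor of mTORC1 signalling (4.62-fold), the retinal reductase gene DHRS3 (log2 difference -2.20), IGDCC3 (at least 3.01-fold) and the antiviral gene IFIT1 (at least 2.11-fold). NRP1, a co-receptor for semaphorins and VEGF, fell at least 3.52-fold on the probe tested (-0.08, not called, on the other), and TLCD1 and PWWP3A fell by 2.07 and 1.94 on the log2 scale. Among probes without a gene symbol, ILMN_1701918 fell at least 4.47-fold and ILMN_1697232 at least 2.00-fold.

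Several lists of signalling and early response genes were called as rising at 8 h. Immediate early genes rose in 21 of 28 (22 adjusted over the list alone, camera adjusted p 2.64e-26), with EGR1 at 3.67. MAPK feedback regulators rose in 12 of 13 (13 adjusted over the list alone; 4.31e-17), among them DUSP5 (2.64), IER3 (2.14), ERRFI1 (2.12) and SPRY4 (2.00). Calcium and cAMP response genes rose in 10 of 15 and fell in 1 (11 and 1 adjusted over the list alone; 3.59e-12), with GEM (3.79; at least 7.78-fold), HOMER1 (2.90) and NFIL3 (1.70). NF-kappaB targets rose in 9 of 20 and fell in 3 (the same counts adjusted over the list alone; 5.41e-06), with CCL2 at 2.72 and GADD45B at 2.63. SRF and YAP/TEAD targets rose in 10 of 17 and fell in 1 (10 and 1 adjusted over the list alone; 5.41e-06), with CCN1 (3.12), CCN2 (2.68), THBS1 (at least 2.86-fold) and TPM4 (1.78).

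Most growth and survival lists had members moving both ways at 8 h. Of 26 growth arrest genes, 8 rose and 6 fell (9 and 7 adjusted over the list alone, camera adjusted p 0.417): CDKN1A, a cyclin-dependent kinase inhibitor, rose by 1.43 and GADD45A by 1.33, and CCNG2 fell by 1.37. Of 21 pro-apoptotic genes, 4 rose and 8 fell (6 and 9 adjusted over the list alone, camera adjusted p 0.993), CASP9 (1.76) and PMAIP1 (1.65) rising and HRK (-1.02) and CASP6 (-0.96) falling. Among 14 anti-apoptotic genes MCL1 rose (0.91) and CFLAR (-0.94) and BIRC5 (-0.48) fell (1 and 2 also adjusted over the list alone, camera adjusted p 0.546). Of 19 p53 targets, 3 rose and 5 fell by either count (camera adjusted p 0.993), SESN1 (-1.05), XPC (-0.87) and BAX (-0.80) among the falls; BAX gave -0.47 (adjusted p 0.188) without triptorelin 8 h replicate 3. G1/S genes rose in 2 of 29 and fell in 6 (4 and 6 adjusted over the list alone, camera adjusted p 0.628), with POLA2 at -0.72 and MCM5 at -0.60. Of 32 G2/M genes 8 fell and 0 rose by either count, HMMR (-1.20), MKI67 (-0.84) and CENPF (-0.66) among them (camera adjusted p 0.124).

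ER stress and amino acid response genes rose in 14 of 24 at 8 h and fell in 1 (18 and 1 adjusted over the list alone), with the chaperone gene HSPA5 at 3.03, PDIA4 at 2.02 and MANF at 1.77. The camera adjusted p of 2.05e-08 became an adjusted p of 0.118 with an estimated correlation. Ribosome biogenesis genes rose in 8 of 19 by either count, RRN3 (0.97) and RRP12 (0.94) among them (camera adjusted p 0.000334, and adjusted p 0.0868 with an estimated correlation). Secreted factors rose in 5 of 13 and fell in 1 by either count (camera adjusted p 0.0151, and 0.0991 with the stricter filter on dim probes), with HBEGF (1.70) and BMP2 (1.55) rising and WNT5A (-1.68) falling. Matrix and protease genes rose in 7 of 18 and fell in 2 by either count (0.00196), with SERPINE2 (1.64), TIMP3 (1.60) and TNC (1.45). The median of the matrix list was 0.28 within hybridisation batch 1 and -0.03 within batch 2. Neuronal and neuroendocrine genes rose in 5 of 14 and fell in 1 by either count (0.000183), with TUBB3 (1.87), NEFM (1.76), VGF (at least 1.80-fold) and CHGB (at least 1.45-fold). Hypoxia and glycolysis genes rose in 8 of 22 and fell in 2 (9 and 2 adjusted over the list alone; 0.0991), ANKRD37 (1.58) and NDRG1 (1.34) rising and PFKFB4 (-1.35) falling. No call was made for cholesterol synthesis (3 of 16 rose and 2 fell by either count, camera adjusted p 0.993) or oxidative phosphorylation (1 of 21 fell, NDUFV1 -0.43, and 0 adjusted over the list alone, 0.53). Heat shock genes rose in 3 of 19 and fell in 2 by either count (0.452), and interferon response genes rose in 1 of 13, ISG15 (1.31), and fell in 4 by either count (0.185). Of 7 epithelial genes 1 rose and 3 fell, CLDN7 (-1.09) and KRT19 (-0.86) among them (2 and 3 adjusted over the list alone, 0.382). Among markers of other cell types, S100A4 of the fibroblast list gave -0.85 (adjusted p 0.0467), and CD68 and CD14 of the blood cell list gave 0.67 and 0.51 (adjusted p 0.00138 and 0.0349).

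Limma called 3159 genes at 8 h, 1429 rising and 1730 falling, with 308 and 289 changed at least 2-fold. Of these, 100.0 and 99.7 percent kept their sign within hybridisation batches 1 and 2 (median log2 rises 0.65 and 0.79, against 0.70 over all arrays; median falls -0.70 and -0.68, against -0.69), batch 2 holding 1 treated array. The count was 1743 with only these groups fitted. Of the 72 genes that rose at 1 h, 61 also rose at 8 h, where 8.04 were expected by chance (Fisher's exact p 2.38e-47).

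**Figure D3:**
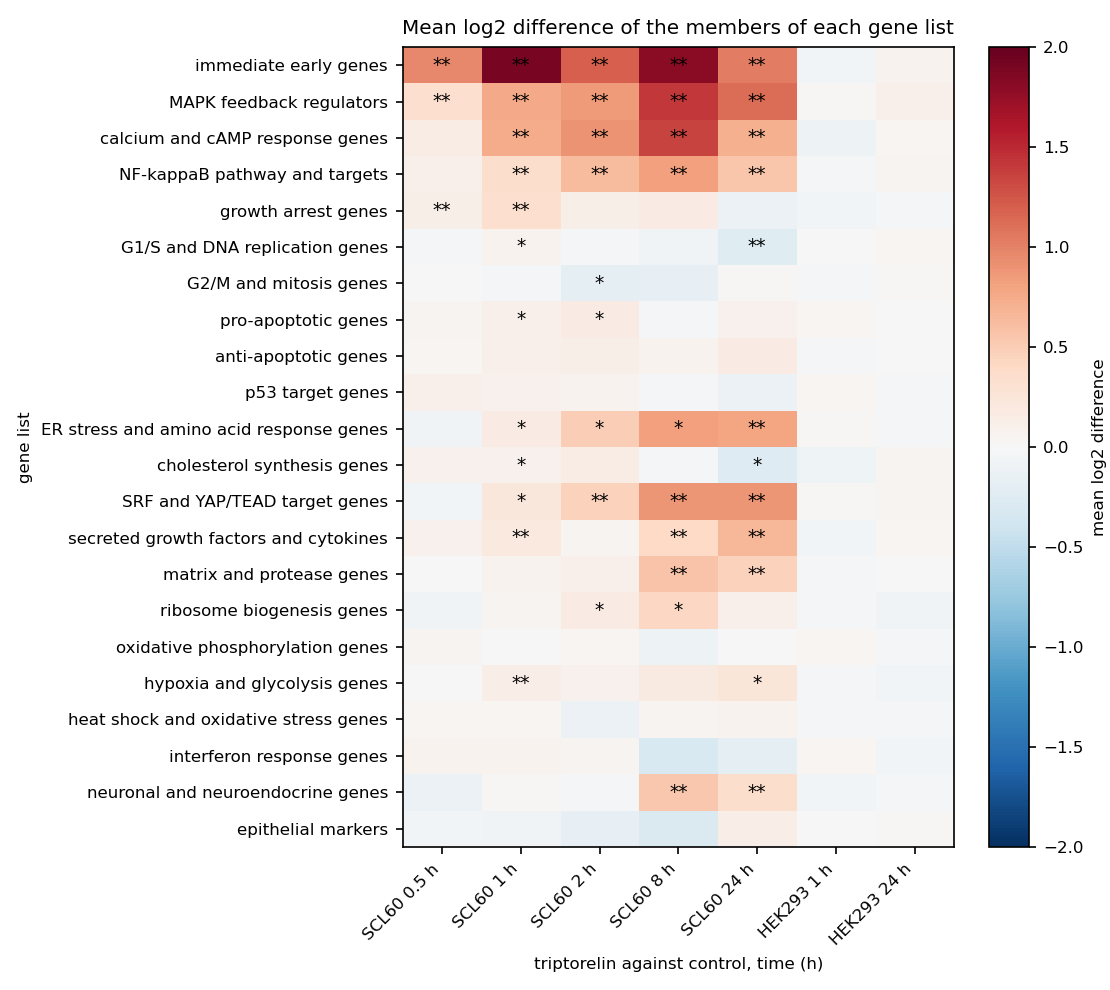
Mean log2 difference (colour) of the tested members of each of 22 gene lists (vertical axis) in the 7 comparisons of triptorelin with control (horizontal axis). A single asterisk marks a camera adjusted p under 0.05 with the preset correlation alone and a double asterisk a call that also held with an estimated correlation; the immediate early list reached a mean of 1.90 in SCL60 at 1 h and -0.05 in HEK293 at 1 h.

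At 24 h, secreted, matrix and growth factor genes stood beside the signalling genes (n = 4 and 4). CGA rose at least 53.9-fold (log2 difference 6.38, SE 0.21, limma adjusted p 7.76e-30), LBH at least 20.8-fold, TAC1 at least 13.3-fold and the ETS transcription factor gene ETV5 at least 12.2-fold. CCN2 and CCN1, matricellular proteins and targets of YAP, rose 19.4-fold and 11.8-fold, the cytokine receptor gene TNFRSF12A 15.3-fold, MMP10 at least 8.83-fold, the neuropeptide gene NTS at least 7.78-fold and the carboxypeptidase gene CPA4 at least 5.98-fold. IGFBP5, an insulin-like growth factor binding protein, fell 11.1-fold (log2 difference -3.47, SE 0.21, adjusted p 1.57e-18), SRGAP3 at least 2.69-fold and AMOT, a regulator of YAP, by 1.81 on the log2 scale. SAMD11, NREP, KIAA1549L and TMEM266 fell by 1.67, 1.59, 1.58 and 1.52 on the log2 scale. ALG1L1P fell by 1.71, the Wnt receptor gene FZD4 at least 2.78-fold and the unnamed probe ILMN_1696846 at least 2.21-fold.

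Immediate early genes still rose in 14 of 28 at 24 h and fell in 1 (16 and 1 adjusted over the list alone, camera adjusted p 1.77e-13), with EGR1 at 3.26 and FOS at least 3.97-fold. MAPK feedback regulators rose in 9 of 13 by either count (5.88e-19), with DUSP5 at least 3.70-fold, IER3 2.27, SPRY4 at least 2.02-fold and DUSP1 1.67. Calcium and cAMP response genes rose in 8 of 15 by either count (2.17e-07), with PTGS2 (2.82), GEM (2.32), STC2 (1.37) and RCAN1 (1.13). NF-kappaB targets rose in 6 of 20 (8 adjusted over the list alone; 0.000119), with CCL2 (3.34), CXCL8 (2.08) and CCL20 (at least 1.39-fold). SRF and YAP/TEAD targets rose in 8 of 17 (10 rose and 1 fell adjusted over the list alone; 2.61e-08), with ANKRD1 at least 3.59-fold and TAGLN at least 1.73-fold. Secreted factors rose in 5 of 13 and fell in 1 (7 and 1 adjusted over the list alone; 1.14e-06), with IL11 (at least 1.87-fold), HBEGF (1.68), GDF15 (1.65) and INHBE (at least 1.09-fold). Matrix and protease genes rose in 5 of 18 (8 rose and 3 fell adjusted over the list alone; 0.000236, and 0.112 with the stricter filter), with MMP9 at least 2.02-fold, SERPINE2 1.31 and LAMB3 at least 1.06-fold.

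DNA replication genes were lower at 24 h, where 5 of 29 G1/S genes fell and 0 rose (8 and 0 adjusted over the list alone, camera adjusted p 0.00145). The 5 were the replicative helicase subunits MCM5 (-0.71), MCM6 (-0.58) and MCM7 (-0.46), the polymerase subunit POLA1 (-0.62) and the DNA repair gene UNG (-0.42), the last named after its value was seen. Of 32 G2/M genes, 2 fell by either count, CENPF (-0.78) and KIF20A (-0.55) (camera adjusted p 0.778). Growth arrest genes rose in 5 of 26 and fell in 9 (5 and 12 adjusted over the list alone; 0.0807), GADD45A (1.16) and CDKN2D (0.98) rising and CCNG2 (-0.98) and SESN1 (-0.98) falling. Of 21 pro-apoptotic genes, BIK (at least 1.26-fold) and PMAIP1 (0.79) rose and BMF (at least 1.14-fold) and DAPK1 (-0.75) fell (2 and 4 adjusted over the list alone, 0.48). None of 14 anti-apoptotic genes passed by either count (MCL1 0.49, adjusted p 0.0842; camera adjusted p 0.104). Of 19 p53 targets, 2 rose and 4 fell (2 and 7 adjusted over the list alone; 0.137), SESN2 (0.90) rising and DDB2 falling at least 1.36-fold.

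ER stress and amino acid response genes rose in 13 of 24 at 24 h by either count (camera adjusted p 6.72e-12, and adjusted p 0.0454 with an estimated correlation), with PPP1R15A (1.83), DDIT3 (1.53), HSPA5 (1.45) and CEBPB (1.39). DDIT3 rose by 2.13 without triptorelin 24 h replicate 2, and HSPA5 gave 0.93 (adjusted p 0.11) without replicate 3. Neuronal and neuroendocrine genes rose in 4 of 14 and fell in 1 (7 and 1 adjusted over the list alone; 0.000539), TUBB3 (1.69), VGF (1.49) and ENO2 (1.10) rising and NPTX1 (-1.12) falling. In the cholesterol synthesis list SQLE (-0.89), LSS (-0.79 on the probe tested and -0.28, not called, on the other) and INSIG1 (-0.73, and -0.06, not called, on the other probe) fell and SC5D (0.56) rose, 3 and 1 of 16 by either count. Its camera adjusted p of 0.018 became an adjusted p of 0.0585 with an estimated correlation. Hypoxia and glycolysis genes rose in 5 of 22 and fell in 3 (6 and 3 adjusted over the list alone, camera adjusted p 0.0236, and adjusted p 0.112 with an estimated correlation), SLC2A3 (1.54) rising and ALDOC (-0.89) falling. No call was made for ribosome biogenesis (1 of 19 rose by either count, RRP12 0.70, camera adjusted p 0.138) or oxidative phosphorylation (0 of 21 by either count, 0.848). Among heat shock genes SRXN1 (0.52) rose and NQO1 fell at least 1.19-fold, 1 and 1 of 19 (2 and 1 adjusted over the list alone, 0.335). In the interferon response list 2 of 13 fell, IFIT1 (-1.47) and IFI44L (at least 1.33-fold), and 1 rose and 2 fell adjusted over the list alone (0.233). Of 7 epithelial genes 2 rose, KRT8 (0.59, and 0.38, adjusted p 0.268, without control 24 h replicate 1) and EPCAM (0.53), and 2 rose and 1 fell adjusted over the list alone (0.264). COL5A1 of the fibroblast list fell at least 1.47-fold, and CD68 of the blood cell list rose by 1.24 on the probe tested (0.11, not called, on the other).

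Limma called 1337 genes at 24 h, 608 rising and 729 falling, with 175 and 73 changed at least 2-fold. With the replicate number as a block, the numbers pairing these samples, the count was 2303, all 1337 among them, and it was 649 with only these groups fitted. All 1337 kept their sign within hybridisation batches 1 and 2 (median log2 rises 0.74 and 0.80, against 0.72 over all arrays; median falls -0.65 and -0.78, against -0.67), batch 2 holding 1 array per group. Of the genes that rose at 8 h, 350 also rose at 24 h (67.9 expected by chance, Fisher's exact p 7.67e-184), and 433 fell at both times (98.6 expected, p 1.41e-201). At 24 h, 36 of the 72 genes that rose at 1 h also rose (3.42 expected, p 7.58e-29).

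In HEK293 cells, which lack the transgene, triptorelin gave no called gene at 1 h or 24 h (n = 4 per group). Limma called 0 of 12793 genes at each time, with 253 and 278 genes at an unadjusted p under 0.05. With the replicate number as a block the counts were again 0. The numbers paired these samples at 1 h but not all of them at 24 h. The log2 differences of the genes that led the SCL60 response were small in HEK293: CGA -0.03 at 1 h and 0.24 at 24 h, FOS -0.46 at 1 h, NR4A2 0.32 at 24 h and CXCL8 0.30 at 24 h, each with an adjusted p of 1. No member of any list passed by either count and no list was called, the lowest camera adjusted p being 0.735 at 1 h and 0.752 at 24 h; the immediate early list had medians of -0.08 and 0.05.

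The difference between the cell lines was tested itself, as the SCL60 effect minus the HEK293 effect. At 1 h, 33 genes had a larger effect in SCL60 and 0 a smaller one (1 without HEK293 control 1 h replicate 2), led by FOSB (6.18, SE 0.46, limma adjusted p 3.13e-14), FOS (4.97), NR4A2 (4.29), EGR3 (4.13) and the unnamed probe ILMN_1743199 (3.89), with CGA at 2.50. FOSB differed by 6.97 without SCL60 control 1 h replicate 3 and FOS by 4.24 without replicate 2. The immediate early list had 14 of 28 members with a larger effect (22 adjusted over the list alone, camera adjusted p 1.3e-131). The MAPK feedback list had 3 of 13 (6 adjusted over the list alone, 3.43e-15), among them DUSP1 (2.87), and the calcium and cAMP list 3 of 15 (5 adjusted over the list alone, 1.08e-19), with PTGS2 (3.68). The NF-kappaB list had 1 of 20 (4 adjusted over the list alone, 2.66e-05), NFKBIZ (1.30), and the growth arrest list 2 of 26 (6 adjusted over the list alone; 1.17e-11), BTG1 (1.27) and GAS1 (1.04). MCL1 (1.92), PPP1R15A (1.36) and TIMP3 (1.45) also differed. Within hybridisation batches 1 and 2 all 33 kept their sign (medians 2.18 and 2.01, against 2.29 over all arrays).

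At 24 h, 247 genes had a higher and 247 a lower effect in SCL60 than in HEK293. CGA (6.15, SE 0.29, limma adjusted p 3.26e-22), TAC1 (4.71), LBH (4.46), CCN2 (4.27) and ETV5 (4.21) had the largest positive differences, and IGFBP5 (-3.70), ILMN_1696846 (-2.25), SRGAP3 (-2.02), AMOT (-1.85) and SAMD11 (-1.70) the largest negative ones. Higher effects were called in 10 of 28 immediate early genes (13 higher and 1 lower adjusted over the list alone, camera adjusted p 6.23e-11), and 8 of 13 MAPK feedback regulators (9 adjusted over the list alone, 6.35e-15). The same held for 4 of 17 SRF and YAP/TEAD targets (8 adjusted over the list alone; 2.67e-06) and 4 of 18 matrix and protease genes (6 adjusted over the list alone; 0.000394, and 0.203 with the stricter filter), with MMP10 at 4.17 and MMP9 at 1.60. Secreted factors had 5 of 13 higher and 1 lower by either count (1.74e-05), IL11 (2.01) and HBEGF (1.88) among them. Neuronal genes had 4 of 14 higher (5 higher and 1 lower adjusted over the list alone; 4e-04), TUBB3 (1.85) and VGF (1.60) among them. The ER stress list (3 of 24 higher, 13 adjusted over the list alone, with PSAT1 at 1.25; camera adjusted p 2.59e-10) had an adjusted p of 0.0571 with an estimated correlation, and the G1/S list (0 of 29 by either count; 0.00165) one of 0.0501. All 494 kept their sign within hybridisation batches 1 and 2 (medians 1.12 and 1.25 for the higher effects, against 1.14 over all arrays, and -0.96 and -1.02 for the lower, against -0.96). The count was 254 with only these groups fitted and 328 without a filter on dim probes. The lower effects were 162 without SCL60 triptorelin 24 h replicate 1 and 153 without HEK293 triptorelin 24 h replicate 1.

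Between 1 h and 8 h the effect of triptorelin in SCL60 cells grew for some genes and shrank for others. It grew for TAC1 (5.78, SE 0.39, limma adjusted p 7.37e-16), MMP10 (5.10), LBH (4.30), C11orf96 (4.04) and CGA (3.78), and shrank for FOSB (-3.59, and -4.38 without SCL60 control 1 h replicate 3), EGR3 (-2.54 on the probe tested, and 0.0362, adjusted p 0.961, under the stricter filter, where another probe stands for it) and EGR4 (-2.26), with LRRC20 (-2.57) and NRP1 (-2.29) also lower. Immediate early genes went both ways, 3 of 28 up, EGR1 (2.40) and ARC (2.36) among them, and 5 down (5 and 6 adjusted over the list alone, camera adjusted p 0.469). EGR1 was itself 2.63 higher in the 1 h than in the 0 h controls, about the size of this growth. The growth of EGR1 was 3.38 without SCL60 control 1 h replicate 2, 1.76 (adjusted p 0.2) without replicate 3 and 1.77 (adjusted p 0.123) without triptorelin 1 h replicate 2. The effect was larger in 4 of 13 MAPK feedback regulators (6 larger and 1 smaller adjusted over the list alone; 5.33e-06), with SPRY4 (1.80) and ERRFI1 (1.57). It was larger in 5 of 15 calcium and cAMP genes and smaller in 1 (6 and 1 adjusted over the list alone, 0.000148), with HOMER1 at 2.94, and larger in 5 of 14 neuronal genes (5 larger and 1 smaller adjusted over the list alone; 0.00025), with NEFM at 2.06. ER stress genes had 5 of 24 larger (7 larger and 1 smaller adjusted over the list alone, camera adjusted p 1.38e-05, and adjusted p 0.269 with an estimated correlation), with HSPA5 at 2.67. The test called 780 genes, 335 with a positive and 445 with a negative difference. Negative differences include falls that came after 1 h, such as that of LRRC20. The count was 485 without SCL60 control 1 h replicate 2, 439 with only these groups fitted and 482 without the filter. Of the 780, 100.0 and 99.9 percent kept their sign within hybridisation batches 1 and 2. Medians there were 1.07 and 1.16 for the positive differences (1.08 over all arrays) and -0.96 and -1.03 for the negative (-1.02 over all arrays).

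From 8 h to 24 h the immediate early and calcium response genes receded. The effect shrank for ARC (-2.60, SE 0.42, limma adjusted p 7.61e-05), NR4A2 (-2.40), C11orf96 (-2.32), NR4A1 (-2.25), HOMER1 (-2.21) and the unnamed probe ILMN_2410145 (-2.67). It was higher at 24 h for DDIT4 (2.08), the muscle gene MYOM1 (1.98), TRIM6 (1.63), C12orf76 (1.63) and ILMN_1701918 (1.76). DDIT4 and ILMN_1701918 had fallen at 8 h, so their higher effects do not by themselves mean rises over control. At 24 h DDIT4 ran from 8.74 to 11.20 with triptorelin and from 10.05 to 11.01 in controls, so the groups overlapped. CGA did not differ by the test (0.14, SE 0.29, adjusted p 0.875). Immediate early genes were lower in 9 of 28 (1 higher and 14 lower adjusted over the list alone, camera adjusted p 5.43e-13). Calcium and cAMP genes were lower in 5 of 15 (2 higher and 8 lower adjusted over the list alone; 2.95e-06), PTGS2 (-1.77) among them. Smaller effects were also called for PDIA4 (-1.53), INSIG1 (-1.44), THBS1 (-1.90), TIMP3 (-1.72) and GADD45B (-1.74). Higher ones were called for INHBE (1.20) and for CLDN7 (1.35), which had fallen at 8 h. The test called 393 genes, 226 higher and 167 lower, all with the same sign within hybridisation batches 1 and 2 (medians 0.98 and 0.96 for the higher, against 1.01 over all arrays, and -0.97 and -1.24 for the lower, against -1.06). With the replicate number as a block, the numbers pairing these samples, the count was 994, all 393 among them. It was 259 without SCL60 triptorelin 8 h replicate 3 (151 higher and 108 lower) and 114 with only these groups fitted.

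The cell lines also differed at 0 h (n = 4 and 4). SCL60 cells were higher in the neural transcription factor gene SOX11 (at least 17.8-fold; log2 difference 5.28, SE 0.16, limma adjusted p 2.76e-31), the keratin gene KRT19 (at least 17.1-fold), the calcium release channel gene RYR3 (at least 15.2-fold), MAL2 (at least 15.3-fold) and the endogenous retroviral gene ERVMER34-1 (13.7-fold). They were lower in the inducible chaperone gene HSPA1A (at least 200.5-fold; log2 difference -8.66, SE 0.23, on a probe no SCL60 array detected, where a silent gene and a sequence difference under the probe were not told apart), CMBL (at least 22.8-fold), the neurofilament gene NEFH (at least 13.8-fold), the carbonic anhydrase gene CA2 (17.7-fold) and the zinc finger gene ZNF83 (at least 8.59-fold). The epithelial list was the 1 list called: 4 of 7 genes were higher (5 higher and 1 lower adjusted over the list alone, camera adjusted p 0.000236), with EPCAM at 2.01 and CLDN7 at 0.99 beside KRT19.

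No other list was called at 0 h with the filter on dim probes. Without it the growth arrest (adjusted p 0.0121), p53 (0.0188) and hypoxia (0.0226) lists were called higher and the heat shock list (0.0123) lower. Neuronal genes were higher in 4 of 14 and lower in 3 (6 and 3 adjusted over the list alone, camera adjusted p 0.807; median 0.23, mean -0.35), UCHL1 at 2.68 against NEFL at -3.12 and NEFM at -2.93. Growth arrest genes were higher in 7 of 26 and lower in 2 by either count (0.304), with the cell cycle inhibitors CDKN2A (2.83-fold), CDKN2B (1.21) and CDKN1A (1.08). MAPK feedback regulators were lower in 4 of 13 by either count (0.182), SPRY2 (-0.82) and SPRED1 (-0.72) among them. Heat shock genes were higher in 2 of 19 and lower in 4 (2 and 6 adjusted over the list alone; 0.182), with HSPA6 at -2.47. CD44 (2.53), the death receptor gene TNFRSF10A (at least 2.83-fold), CCL2 (1.90) and ACTA2 (1.65) were higher and VEGFC (-1.16) lower in SCL60. COL5A1 of the fibroblast list was higher (at least 1.53-fold), while no blood cell marker passed (CD14 -0.49, adjusted p 0.0511). Limma called 2502 genes, 1464 higher and 1038 lower, with 348 and 187 at least 2-fold apart. Of the 2502, 100.0 and 99.0 percent kept their sign within hybridisation batches 1 and 2 (medians 0.71 and 0.81 for the higher, against 0.71 over all arrays, and -0.72 and -0.70 for the lower, against -0.68). With the 0, 1 and 24 h controls of each line in place of those at 0 h alone, the count was 5429, 2479 of the 2502 among them.

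Differences at 0 h were uneven along the genome. Genes on chromosomes 1, 9, 14, 18 and 20 leaned higher in SCL60 (25.3 percent of 292 tested genes called higher and 0.685 percent lower on chromosome 20, median log2 difference 0.28). Genes on chromosomes 8 and 22 leaned lower (23.3 percent of 386 genes called lower on chromosome 8, median -0.29, and 24.3 percent of 255 on chromosome 22, median -0.28). On chromosome 19, 81 of 152 zinc finger genes were lower and 4 higher (median -0.62), against a median of -0.08 for the other 550 genes tested there.

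**Figure D4:**
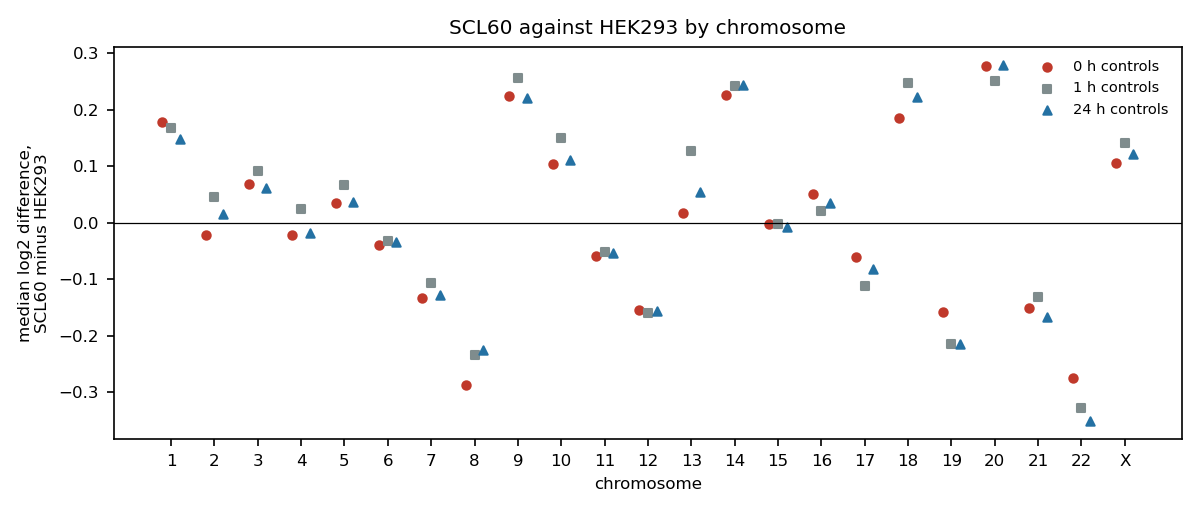
Median log2 difference of SCL60 minus HEK293 (vertical axis) over the tested genes of each chromosome (horizontal axis), in the 0 h, 1 h and 24 h control arrays. Medians at 0 h ran from -0.29 on chromosome 8 to 0.28 on chromosome 20.

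Control cells were compared over time. The sample records do not say whether the 0 h cells had received vehicle or a medium change, so time in culture and handling are not separated here. Between 0 h and 24 h no gene passed in SCL60 or HEK293 controls (limma called 0 of 12793 genes in each, with 179 and 638 at an unadjusted p under 0.05). In SCL60, CGA gave 0.00, EGR1 -1.12 and HSPA5 -0.71, each with an adjusted p of 1. Camera called 3 lists in SCL60, each with 0 called members by either count. These were the MAPK feedback regulators (median -0.14, adjusted p 0.00938, and adjusted p 0.377 with an estimated correlation) and ER stress genes (median -0.24, adjusted p 1.93e-06, and adjusted p 0.578 with an estimated correlation). The last, secreted factors (median -0.17), had an adjusted p of 0.00555, and an adjusted p of 0.0586 with an estimated correlation. In HEK293 no list was called. The hypoxia and glycolysis list (camera adjusted p 0.0505) passed under 5 other settings, the lowest adjusted p being 0.00226 with the chip as a block. The count of genes was 2 without HEK293 control 24 h replicate 3.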

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

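The tests on zinc finger genes of other chromosomes and on their neighbours, on the immediate early list in HEK293 controls and on that list at 24 h were chosen after results were seen; the other tests were fixed before they were run.

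A few arrays stood apart from the other 3 of their group. Before normalization, the 95th percentile of the signal was 778.9 on HEK293 triptorelin 24 h replicate 3 (1519.9 to 1622.2 on the others). It was 1689.9 on SCL60 control 24 h replicate 2 (804.9 to 924.1). The HEK293 array was the only one of its group on chip 1, whose 11 arrays ran from 582.9 to 1026, so its value was ordinary for its chip. SCL60 control 8 h replicate 1 had 11976 detected probes (13875 to 14179), and the probe ILMN_2410145 read 5.09 on SCL60 control 24 h replicate 1 (4.52 to 4.56). These were 4 of 59 groups of values tested for an array far from the rest, where chance marks about 1 in 20 groups. No array was left out. The other values that stood out were counts of genes whose effect differed: 33 between the lines at 1 h, 494 between the lines at 24 h, 780 between 8 h and 1 h and 393 between 24 h and 8 h.

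Genes of many chromosomes leaned to 1 side between SCL60 and HEK293 at 0 h. On 13 of 23 chromosomes the median difference exceeded 0.1 on the log2 scale, up to -0.29 on chromosome 8. The largest in 10000 random reassignments of genes was 0.17, which chromosomes 7, 10, 12, 19, 21 and X of the 13 did not reach. Without its zinc finger genes chromosome 19 had a median of -0.08. An array batch at 0 h was argued against by the 13 chromosomes that kept their sign in both the 1 h and the 24 h controls. A different copy number of the chromosomes in the 2 lines could give such shifts. On 13 of the 13 both the bright and the dim genes leaned to the chromosome's side, but the chromosomes had been chosen on these same genes, so this says nothing for or against it. Copy number was not measured here, and it and other causes stay open.

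Zinc finger genes of chromosome 19 were lower in SCL60 at 0 h, 81 of 152 with a median of -0.62. An array batch was argued against by the 24 h controls, where the same genes had a median of -0.56. A change of zinc finger genes as large on every chromosome was argued against by the other 186, with a median of -0.0863. The share that fell differed (Fisher's exact p 1.98e-14, a test that takes genes as independent). A smaller lean elsewhere was not argued against: 27 of the 186 were lower and 11 higher, while of all 12793 genes 1038 were lower and 1464 higher. Fewer copies of the region could not be told from a change of the family there: 30 neighbours of other families had a median of -0.26 (quartiles -0.74 and -0.03), 10 of them lower. Whether copies, chromatin or cell history underlies the falls stays open.

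Immediate early genes were higher in the controls at 1 h than at 0 h: CCN1 (2.66), EGR1 (2.63) and FOSB (1.73) rose in SCL60, and EGR1 (2.91) and FOS (1.77) in HEK293. The MAPK feedback regulator DUSP5 (1.61 and 1.26) was the 1 other gene limma called in each line. Traces of triptorelin in the control cultures were argued against as a cause in HEK293, where the list's median was 0.30 (26 of 28 genes higher) against 0.24 in SCL60. The rise in HEK293 cannot exclude added traces in an SCL60 culture. On SCL60 control 1 h replicate 3, FOSB read 9.27 (6.79 and 7.01 on the others) and NR4A2 read 6.67 (5.64 and 5.52). These genes were looked at after the values had been seen. The chip and the labelling batch were argued against by medians of 0.24 and 0.23 with these as blocks. A brief response to handling or vehicle could leave the list back at its 0 h level later, and at 24 h its median was -0.0390. Whether the 0 h cells had received vehicle or a medium change is not stated, so handling and vehicle were not separated by these samples.

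Splits of the same arrays into other groups tested whether chance divisions give as many genes. In 1 of 35 splits, the real one, the count was reached at 0.5 h (14 genes, highest other 13), 1 h (72, 34), 2 h (190, 98), 8 h (3159, 1943), 24 h (1337, 117) and between the lines at 0 h (2502, 100). Among splits that part as many same-number pairs, the highest others were 2, 19, 45, 126 and 26 for the 5 times of triptorelin. With 0 genes in the real division, all 35 splits reached the count in HEK293 at 1 h (highest other 2) and 24 h (0) and between the 24 h and 0 h controls of SCL60 (0) and HEK293 (11).

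For differences of effects, 2 of 100 splits reached the 33 genes between the lines at 1 h (highest other 33), 5 of 100 splits the 494 genes at 24 h (748), 3 of 100 splits the 780 genes between 8 h and 1 h (1623) and 5 of 100 splits the 393 genes between 24 h and 8 h (1631). Arrays exchanged within a time still carry a treatment effect in such splits, so these counts neither exclude chance nor speak for it. The other split that reached 33 and all 4 that reached 494 kept the real groups of 1 line, and the highest counts with neither line kept were 13 and 2. With neither time kept the highest were 1623 between 8 h and 1 h and 1067 between 24 h and 8 h. Among the few splits parting as many same-number pairs as the real one, the highest other counts between the lines were 0 at 1 h and 0 at 24 h. They were 6 between 8 h and 1 h and 792 between 24 h and 8 h. The cause of the high counts was not tested.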

How the results depend on the processing

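All tests under other settings were set before results were seen. Of 506 named results that passed, 390 passed under every setting in which the gene was tested, and 405 without each array in turn. Of 349 that did not pass, 321 and 335 stayed so. Genes removed by the stricter filter, CGA among them, were not tested under it, so these counts say nothing of them there. With an estimated correlation 27 of 308 list results lost their call. Under the other settings 11 of the 85 called list results lost their call and 40 of the 223 others gained one, 19 of them with no filter. The cause of these moves was not tested.

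With only the groups compared in the fit, counts went from 14 to 5 at 0.5 h, 72 to 43 at 1 h, 190 to 80 at 2 h, 3159 to 1743 at 8 h and 1337 to 649 at 24 h, from 494 to 254 for the difference of the lines at 24 h, and from 780 to 439 (8 h minus 1 h) and 393 to 114 (24 h minus 8 h). With the replicate number as a block they were 422 at 2 h, 2303 at 24 h, 1054 for the difference of the lines at 24 h, 1575 for 8 h minus 1 h and 994 for 24 h minus 8 h, and 8 lists gained and 3 lost a call; the numbers did not pair all samples of the difference of the lines or of 8 h minus 1 h. With the labelling batch as a block they were 331 at 2 h, 769 for the lines at 24 h and 635 for 24 h minus 8 h. With no filter they were 328 for the lines at 24 h and 482 for 8 h minus 1 h. Against 0 h controls 26 genes passed at 0.5 h, against the mean of 0 h and 1 h controls 28 at 0.5 h and 447 at 2 h, and with all controls 5429 between the lines. The share rising at 2 h, 71.1 percent, was 60.0 with the replicate block, 61.0 with the labelling block, 88.8 with only the groups compared and 59.7 with the mean controls; for the lines at 24 h it went from 50.0 to 60.6 with only the groups compared. Without background correction the genes changed at least 2-fold went from 308 up and 289 down to 179 and 115 at 8 h and from 175 and 73 to 103 and 26 at 24 h, from 75 and 6 to 53 and 2 at 2 h, from 348 and 187 to 179 and 98 between the lines at 0 h and from 159 and 106 to 95 and 33 for the lines at 24 h. They went from 205 and 230 to 122 and 110 for 8 h minus 1 h and from 115 and 100 to 37 and 58 for 24 h minus 8 h. EGR3 turned from -2.54 to 0.0362 (adjusted p 0.961) in 8 h minus 1 h under the stricter filter, where another probe stands for it. Leaving out an array gave 46 to 67 genes at 1 h and 485 to 861 for 8 h minus 1 h, both lowest without SCL60 control 1 h replicate 2. It gave 101 to 186 at 2 h, lowest without SCL60 control 1 h replicate 4, 259 to 481 for 24 h minus 8 h, lowest without SCL60 triptorelin 8 h replicate 3, and up to 2 for the HEK293 controls without 24 h replicate 3.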

Other observations

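The tests of heat shock genes given here were picked out after results were seen, and the others were set before.

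Heat shock genes of the HSP70 family read differently by probe between the lines. HSPA1A was detected on 0 of 35 SCL60 arrays (mean log2 value 4.51) and on 20 of 20 HEK293 arrays (13.3), while its near-identical neighbour HSPA1B was detected on every array of both (13.4 and 14.0; difference at 0 h -0.42, SE 0.33, adjusted p 0.417). A silent gene and a sequence difference under the HSPA1A probe were not told apart here. HSPA6, a stress-induced relative, was detected on 21 of 35 SCL60 and 20 of 20 HEK293 arrays, and the constitutive HSPA8 was 0.45 higher in SCL60 (adjusted p 0.00526).

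After the groups were accounted for, the first component of the remaining variation held 25.9 percent of it. The replicate number accounted for 0.864 of that component, the labelling batch for 0.823, the chip for 0.313 and the hybridisation batch for 0.223. Each replicate number but the first lay within a single labelling batch, so replicate number and labelling batch were not told apart. The second component held 18.5 percent, with 0.578 for the replicate number. Same-number arrays of treated and control groups correlated in SCL60 at every time, with medians from 0.296 at 8 h to 0.555 at 24 h.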
